A study of Homo sapiens with 12 samples.

How the data were processed

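RNA-seq was run on 12 libraries from KYSE510 and TE7, 2 human cell lines derived from esophageal squamous cell carcinoma. Per the labels' protocols, KYSE510 grew in RPMI-1640 and TE7 in DMEM, and total RNA came from an RNeasy kit. Polyadenylated RNA went into TruSeq libraries that were sequenced on an Illumina HiSeq, per the labels. Each line gave 1 library in each of 6 conditions: DMSO, THZ1 at 50 nM for 2, 4, 6 and 12 h, and THZ1 at 200 nM for 6 h. THZ1 binds CDK7 covalently, and CDK12 and CDK13 at higher doses. Each DMSO library is titled 0 h while its time label says 12 h. Here it served as the untreated control, at 0 h in the trend. No DMSO library is labelled 2, 4 or 6 h. Changes with hours, also from 2 to 12 h and in the trend, thus cannot be told apart from handling or time in culture.

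The authors deposited gene tables in FPKM, with the columns of a Cufflinks gene table per the file headers. STAR, Cufflinks and the hg19 genome are named per the submitters' processing notes; their versions, settings and gene annotation are not given in the sources used here. The 95% bounds that the authors' tables give for each FPKM served to describe depth only. Each table had 57869 lines for 57755 gene identifiers, and the 108 identifiers listed at several loci were summed. Gene biotypes came from GENCODE 29 by identifier, which matched 52328 of them (90.6%); coordinates are those of the authors' tables on hg19. A table of the whole series repeats these values with damaged signs in small numbers and was not used.

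FPKM summed to 383975 to 729515 per library, and 11685 to 13982 genes reached 1 FPKM. Fragment totals are not given in the sources used here. Genes whose interval was that of a single fragment put the depth of each library at 0.833 to 1.02 of that of the TE7 DMSO library. In the median gene at or above 1 FPKM the upper bound lay 7.29% to 10.6% above the value, which covers counting error only.

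Values were analysed as log2(FPKM + 1), so changes of genes with low FPKM are understated. The 15610 genes with at least 1 FPKM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3. The model had a term for each condition and a cell-line block, with moderated variances that follow the mean (trend=TRUE). Tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The same-numbered libraries of all conditions come from the same cell line, so the pairing holds by design; 5 residual degrees of freedom were left, plus 2.86 from the prior. The time trend used the 10 libraries of DMSO and 50 nM with a slope per line, 6 residual degrees of freedom and 2.56 from the prior. Each condition has 1 library per line and the lines stood in as the 2 replicates, so p-values measure only the spread between these libraries and lines.

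Gene lists were tested with camera at a preset correlation of 0.01, with the estimated correlation as an alternative, and with fry, which asks whether a list's genes move on balance one way. Camera ranks a list against the other genes, so its direction is relative. Of 34 lists, 32 had at least 5 tested members. The leukocyte list had 1 tested gene, CD68, and the endothelial list had 0. Members were also adjusted over each list alone. The list of super-enhancer genes (PAK4, RUNX1, DNAJB1, SREBF2, YAP1) was chosen by the study's own aim.

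Lists, model, thresholds, comparisons and gene-naming rule were set before the data were examined. For each contrast with DMSO and for the dose contrast the rule took genes with a mean FPKM of at least 5 and an ordinary symbol. The 10 with the largest rise and the 10 with the largest fall were ranked by the smaller of the changes in the 2 lines. It added the super-enhancer genes, CDK7, CDK12, CDK13, and up to 4 members per list; for line differences it took the 10 largest per direction past the threshold. The texts name a subset of these, and some that the rule selects are not reported here. CSRNP1 at 2 h, EDN2, DBP, CCNG2 and JRKL at 4 h, the nuclear genes PRSS3, CRIP1, CA2 and TUSC3 in the line comparison, and the non-coding genes listed by level were picked after their values were seen. The comparison of 12 h with 2 h, a fit without 3 libraries that stand apart, and scaling over nuclear protein-coding genes were added after the data were seen.

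Alternatives were the highest locus in place of the sum of loci, pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, rescaling to equal sums of FPKM, median-of-ratios and upper-quartile scaling, and variances with no mean trend or with robust estimation. Others left out 1 library at a time, left out the block, took log2 hours in the trend, or left out the 12 h or DMSO libraries there. The closing part gives their effect.

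The condition contrasts and trend terms were tested on simulated data with 200 of 15610 genes changed. The line comparison and the list tests were not simulated. Changed genes were drawn from those with a mean log2(FPKM + 1) over 2, and each gene had the same spread in every library. False calls numbered 2 to 9 per comparison. For 12 h against DMSO, 17.9% of genes changed by log2 1, 77.6% of those changed by 2 and 86.4% of those changed by 3 were recovered. For 2 h against DMSO the shares were 13.4%, 68.7% and 83.3%, for 4 h 11.9%, 70.1% and 78.8%, and for 6 h 10.4%, 65.7% and 92.4%. At 200 nM they were 14.9%, 67.2% and 81.8% against DMSO and 20.9%, 61.2% and 90.9% against 50 nM. For 12 h against 2 h they were 10.4%, 53.7% and 89.4%, for the shared trend 53.7%, 82.1% and 93.9%, and for the slope difference 3%, 22.4% and 75.8%. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.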

Results

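The data are FPKM values for 12 RNA-seq libraries from KYSE510 and TE7 cells, with 6 conditions and 1 library per line and condition. FPKM summed to 383975 to 535976 in the KYSE510 libraries and to 459201 to 729515 in the TE7 libraries. Changes below are log2 means over the 2 lines (n = 2) with the limma standard error, and "adjusted p" is limma's.

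In KYSE510, 50 genes at or above 8 FPKM in DMSO stood under 0.3 FPKM in the 50 nM libraries, and 61 genes did the opposite. In TE7 there were 4 and 1 such genes. CASC19 and CCAT1, named below as higher at 50 nM, are among the 61 in KYSE510. By the same bounds the 200 nM library alone was low in 71 genes and high in 27 in TE7, and in 9 and 21 in KYSE510. The neuronal hydrolase gene UCHL1 (4, 41258430 to 41270472) just missed the bound of 0.3 FPKM. It was 0.32 FPKM in the library labelled KYSE510 DMSO and 335 FPKM after 2 h. Across genes the library labelled KYSE510 DMSO correlated with the 2 h library at r = 0.879, against 0.976 in TE7. Every direction against DMSO below draws on that library. Both 200 nM libraries also stood apart, with r = 0.855 and 0.865 to the 50 nM library of their own line at 6 h.

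**Figure D1:**
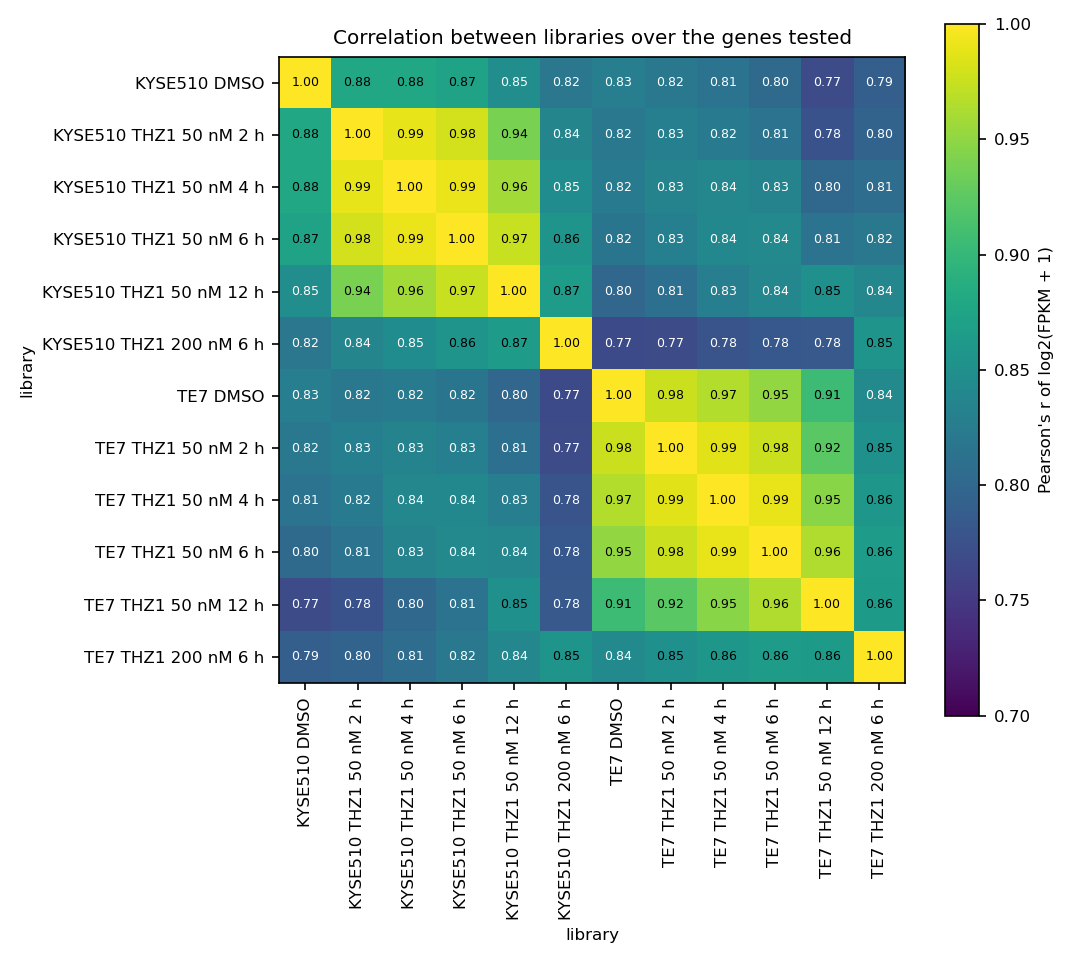
Pearson correlation across tested genes of log2(FPKM + 1) between all 12 libraries, with lines and conditions on both axes and colour for r. The library labelled KYSE510 DMSO reaches 0.879 with its closest treated library, and the 200 nM libraries of the 2 lines reach 0.855 with each other.

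The 2 h comparison asked which transcripts differ first under 50 nM THZ1, with no DMSO library at 2 h to set apart handling or time in culture. FOSL1 (ENSG00000175592; 11, 65659520 to 65668044), which encodes an AP-1 subunit, rose by 3.36 ± 0.23 (adjusted p = 0.00912), from 10.2 to 157 FPKM in KYSE510 and from 41.3 to 316 FPKM in TE7. CSRNP1 (ENSG00000144655; 3, 39183346 to 39196053), an AXIN1-induced nuclear protein gene, rose by 2.39 ± 0.21 (adjusted p = 0.0324). These were the only genes past the threshold, 2 up and 0 down by limma, while 1683 genes had an unadjusted p under 0.05. Among immediate-early genes 1 of 26 rose and 0 fell, or 12 and 0 adjusted over the list alone, with a list median of 1.07 and a camera adjusted p = 4.53e-13 (adjusted p = 0.109 with an estimated correlation). EGR3 (3.75 ± 0.46), NR4A1 (3.12 ± 0.73), KLF4 (2.59 ± 0.69) and ATF3 (2.47 ± 0.46) lay higher in both lines without passing over all genes.

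Further lists were shifted upward by camera at 2 h, with 0 members past the threshold over all genes. Receptor tyrosine kinase and MAPK feedback genes had 0 of 24 up and 0 down, or 6 and 1 adjusted over the list alone, and were shifted upward by camera (adjusted p = 0.000129, adjusted p = 0.109 with an estimated correlation). HBEGF and AREG encode EGF receptor ligands and stood at 2.36 ± 0.53 and 2.12 ± 0.43, while the feedback inhibitors SPRY2 and ERRFI1 stood at 1.99 ± 0.47 and 1.80 ± 0.33. The p53 targets PLK3 (2.32 ± 0.24, adjusted p = 0.0664), AEN (adjusted p = 0.236) and CDKN1A (1.15 ± 0.33) belonged to a list with 0 of 20 members changed, 5 up adjusted over the list alone, and a camera adjusted p = 2.89e-05 (adjusted p = 0.218 with an estimated correlation). CCNE1 (1.66 ± 0.35) and CCNE2 (1.43 ± 0.36) stood for G1/S genes (0 of 27; 1 over the list alone; camera adjusted p = 2.77e-06, adjusted p = 0.485 with an estimated correlation). NOP2 (0.97 ± 0.20) stood for ribosome biogenesis genes (0 of 29; 2 over the list alone; camera adjusted p = 1.5e-05, adjusted p = 0.519 with an estimated correlation). The non-coding MIR22HG (3.19 ± 0.48), CASC19 (3.61 ± 0.67) and CCAT1 (4.63 ± 1.03) were higher in both lines, with CCAT1 at 7.11 in KYSE510 and 2.15 in TE7.

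Integrated stress response genes went both ways at 2 h, with 0 of 24 changed, or 2 up and 2 down over the list alone. DDIT4 (ENSG00000168209; 10, 74033678 to 74035794), an mTORC1 inhibitor gene, was at -2.98 ± 0.38 (adjusted p = 0.113), from 162 to 13.3 FPKM in KYSE510 and from 96.4 to 16.7 FPKM in TE7. NDRG1 (-2.31 ± 0.40), PFKFB4 (-1.87 ± 0.33), CA9 (-5.33 in KYSE510 and -0.90 in TE7) and EGLN3 (-2.29 ± 0.86) belonged to the hypoxia list, with 0 of 24 changed, 1 up and 6 down adjusted over the list alone, and a camera adjusted p = 5.51e-07 (adjusted p = 0.218 with an estimated correlation). ARRDC3 (-1.88 ± 0.21, adjusted p = 0.0986), MKNK2 (-1.51 ± 0.26) and the basal keratin KRT15 (-2.19 ± 0.50) did not pass either. KIF20A (-1.45 ± 0.23) and HMMR (-1.02 ± 0.19) stood for mitosis genes, 0 of 30 changed, 2 down over the list alone, camera adjusted p = 1.52e-05 (adjusted p = 0.519 with an estimated correlation). Ribosomal protein genes (0 of 83) had a camera adjusted p = 2.78e-09 downward (adjusted p = 0.284 with an estimated correlation).

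Cholesterol synthesis genes at 2 h hung on the library labelled KYSE510 DMSO. Their median was -1.62 in KYSE510 and -0.12 in TE7, and camera placed the list lower (0 of 24 changed, 1 up over the list alone, adjusted p = 1.5e-05, adjusted p = 0.519 with an estimated correlation). DHCR7, for a sterol reductase, was at -4.90 in KYSE510 and 0.19 in TE7. KRT6A, another keratin, was at 6.60 in KYSE510 and 0.92 in TE7. CDK7, the target of THZ1 (ENSG00000134058; 5, 68530668 to 68573250), was at -0.01 ± 0.36, CDK12 at 0.23 ± 0.22 and CDK13 at -0.04 ± 0.25. PAK4 (-0.26 ± 0.29) did not pass. The lines parted for 4 genes that did not pass either, YAP1 (-1.25 in KYSE510 and 0.04 in TE7), DNAJB1 (1.05 and -0.18), RUNX1 (-0.62 and 1.20) and SREBF2 (-1.75 and -0.15).

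Both 2 h calls ended without the library labelled KYSE510 DMSO or any 1 of the 50 nM libraries (0 genes), or with no block (0), and without the TE7 DMSO library 1717 genes passed. Without the 3 libraries that stand apart, where DMSO is the TE7 library alone, 195 genes passed, 88 up and 107 down, and after median-of-ratios scaling 1 did.

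The 4 h comparison asked how the early response went on. FOSL1 was still raised, by 2.89 ± 0.23 (adjusted p = 0.0289). DDIT4 fell by 3.22 ± 0.38 (adjusted p = 0.0436), and VAV3 (ENSG00000134215; 1, 108113782 to 108507766), for an exchange factor, fell by 2.47 ± 0.23 (adjusted p = 0.042). CCNG2 (-2.47 ± 0.26), for an atypical cyclin, the clock gene DBP (-2.22 ± 0.24), the endothelin gene EDN2 (-2.30 ± 0.27), JRKL (-2.23 ± 0.26) and C12orf65, for a mitochondrial release factor (adjusted p = 0.0421), also fell. By limma 12 genes passed, 4 up and 8 down, and 2466 had an unadjusted p under 0.05.

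Ribosome biogenesis genes were shifted upward at 4 h with 0 of 29 changed over all genes and 10 up adjusted over the list alone (camera adjusted p = 6.05e-08, adjusted p = 0.588 with an estimated correlation). NOP16 stood at 1.08 ± 0.19 (adjusted p = 0.0763) and UTP15 at 1.11 ± 0.24. Mitosis genes had 0 of 30 changed and 6 down over the list alone (camera adjusted p = 0.000611, adjusted p = 0.735 with an estimated correlation), with HMMR at -1.30 ± 0.19 and KIF20A at -1.46 ± 0.23. Immediate-early genes kept 1 up, 3 over the list alone (camera adjusted p = 0.0329, adjusted p = 0.591 with an estimated correlation). CASC19 (4.47 ± 0.67), CCAT1 (4.66 ± 1.03), MIR22HG (3.59 ± 0.48), PPP1R10 (-2.97 ± 0.43), for a phosphatase 1 subunit, and PLEKHH3 (-2.02 ± 0.26) had an adjusted p of 0.066 to 0.108. CDK7 (0.04 ± 0.36), CDK12 (0.17 ± 0.22), CDK13 (-0.41 ± 0.25), PAK4 (-0.28 ± 0.29), YAP1 (-0.74 ± 0.36) and SREBF2 (-0.98 ± 0.44) did not pass.

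All 12 calls at 4 h ended without the library labelled KYSE510 DMSO, without any 1 of the 50 nM libraries, with no block, after rescaling to equal sums or after scaling over nuclear protein-coding genes (0 genes each). The count was 1991 without the TE7 DMSO library, 308 and 309 without the KYSE510 or TE7 200 nM library, 1 after median-of-ratios scaling, and 1665 without the 3 libraries that stand apart.

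The 6 h comparison asked what followed the early response. DDIT4 fell by 3.58 ± 0.38 and PLEKHH3 by 2.89 ± 0.26, and VAV3 fell with them (adjusted p = 0.0156 for each). PPP1R10 fell by 3.30 ± 0.43 (adjusted p = 0.018), MOB3A by 2.91 ± 0.39, TTC9C by 2.85 ± 0.39, NABP1, for a single-strand DNA binding protein, by 2.83 ± 0.48, GOLPH3L by 2.55 ± 0.32, and ZC3H4, for a zinc finger protein that restrains non-coding transcription, by 2.48 ± 0.28. MIR22HG (3.93 ± 0.48), CASC19 (4.65 ± 0.67), FST (2.83 ± 0.56), ZNF587B (2.55 ± 0.39), FOSL1 (2.17 ± 0.23) and PHLDA2 (2.08 ± 0.47) rose, while CCAT1 (4.36 ± 1.03, adjusted p = 0.0553) did not pass. By limma 736 genes passed, 108 up and 628 down; after median-of-ratios scaling the split was 109 up and 250 down.

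Of 30 mitosis genes 6 fell and 0 rose at 6 h, 10 down over the list alone (camera adjusted p = 0.00186, adjusted p = 0.688 with an estimated correlation). HMMR, for a spindle protein, fell by 1.68 ± 0.19 (adjusted p = 0.0159), KIF20A by 1.63 ± 0.23 and AURKA by 1.66 ± 0.30. C2H2 zinc finger genes had 43 of 351 down and 2 up, 83 and 7 over the list alone, with ZNF691 (-2.11 ± 0.23) and ZNF302 (-1.89 ± 0.31) as examples (camera adjusted p = 0.002, adjusted p = 0.688 with an estimated correlation). BLM (-2.19 ± 0.30) and FANCF (-1.92 ± 0.28) were the 2 of 34 homologous recombination genes that fell, 4 over the list alone (camera adjusted p = 0.345). Hypoxia genes had 3 of 24 down, 4 over the list alone, PFKFB4 (-2.30 ± 0.33) and NDRG1 (-2.09 ± 0.40) among them. CEBPB (-2.99 ± 0.42), the apoptosis promoters APAF1 (-1.68 ± 0.22) and BMF (-1.77 ± 0.25), the splicing kinase gene CLK2 (-1.54 ± 0.25) and KRT15 (-2.27 ± 0.50) fell as well.

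Transcription genes had 1 of 33 up and 0 down at 6 h, 1 and 0 over the list alone, with 16 members higher and 17 lower (camera adjusted p = 0.441). POLR2A, the large subunit gene of RNA polymerase II (ENSG00000181222; 17, 7387685 to 7417933), rose by 1.40 ± 0.20 (adjusted p = 0.0184), from 47.3 to 109 FPKM in KYSE510. MED13 of the Mediator kinase module rose by 1.38 ± 0.20 and ATF5 by 1.98 ± 0.28, whereas MED7 (-1.52 ± 0.35, adjusted p = 0.0516) did not pass. Ribosome biogenesis genes had 2 of 29 up, DDX21 (1.07 ± 0.21) and NOP16 (1.06 ± 0.19), and 6 over the list alone (camera adjusted p = 2.89e-07, adjusted p = 0.688 with an estimated correlation). CDK7 (-0.04 ± 0.36), CDK12 (0.04 ± 0.22), CDK13 (-0.78 ± 0.25), PAK4 (-0.42 ± 0.29), YAP1 (-0.91 ± 0.36), DNAJB1 (-0.53 ± 0.47) and SREBF2 (-0.91 ± 0.44) did not pass.

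The 6 h count was 0 with no block or without any 1 of the 2, 4 or 6 h libraries at 50 nM. It was 354 without the library labelled KYSE510 DMSO, 2556 without TE7 DMSO, 352 and 351 without the KYSE510 or TE7 12 h library, 1840 and 1827 without the KYSE510 or TE7 200 nM library, and 3819 without the 3 libraries that stand apart.

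The 12 h comparison had the widest response at 50 nM. LPCAT1 (ENSG00000153395; 5, 1456595 to 1524092), for a phospholipid acyltransferase, fell by 3.54 ± 0.32 (adjusted p = 0.00108) and MOB3A by 3.81 ± 0.39 (adjusted p = 0.00128). FAM208A, for a subunit of a silencing complex (-3.29 ± 0.25), the iron-sulfur gene ISCA2 (-3.15 ± 0.31), the primase gene PRIM1 (-3.04 ± 0.45), the channel gene KCNN4 (-3.33 ± 0.65) and GPRC5C (-3.29 ± 0.36) fell as well. NXF1 (ENSG00000162231; 11, 62559595 to 62573774), the mRNA export receptor gene, rose by 2.35 ± 0.26 (adjusted p = 0.00144), from 20.6 to 151 FPKM in KYSE510 and from 46.2 to 173 FPKM in TE7. EID3 (3.55 ± 0.60), CASC19 (4.13 ± 0.67), MIR22HG (3.67 ± 0.48), KLHL11 (adjusted p = 0.00241) and UGGT2 (2.32 ± 0.39) rose too. By limma 4439 of 15610 genes (28.4%) passed, 510 up and 3929 down; with median-of-ratios scaling the split was 1455 up and 2003 down and with upper-quartile scaling 1473 and 1942.

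**Figure D2:**
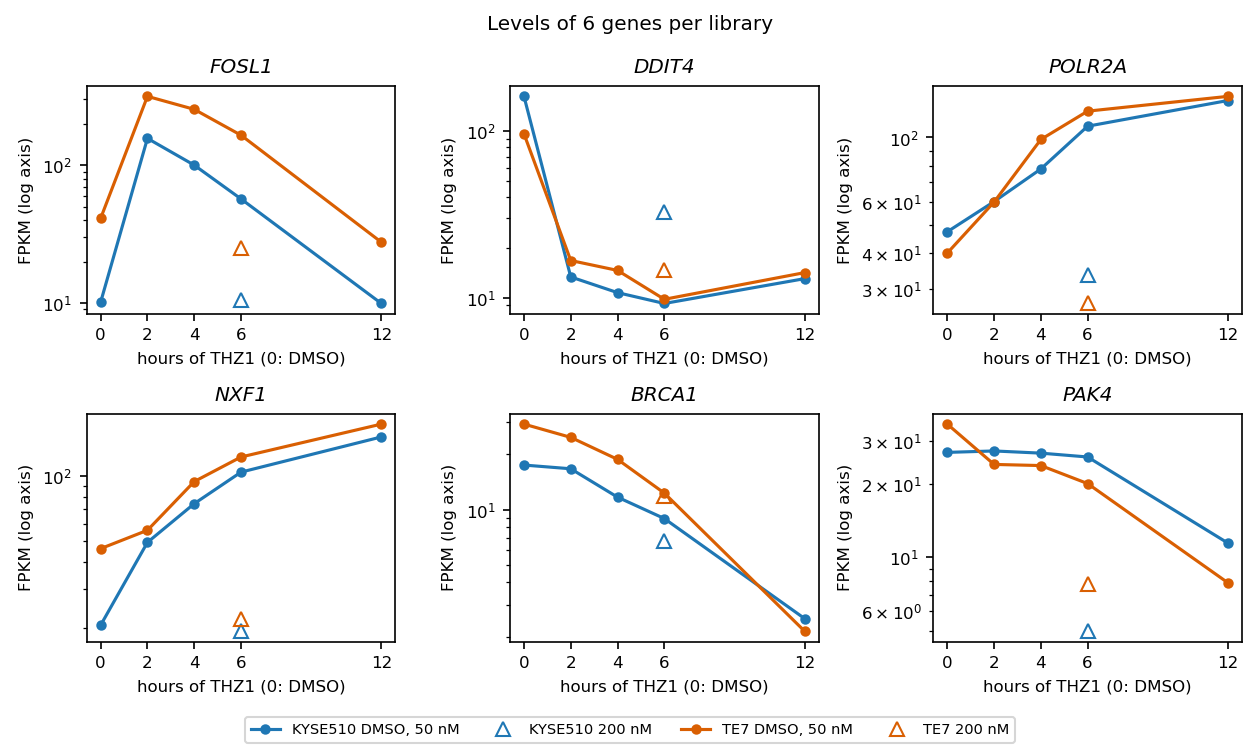
FPKM on a log axis against hours of 50 nM THZ1 for FOSL1, DDIT4, POLR2A, NXF1, BRCA1 and PAK4, with a line per cell line and separate points for 200 nM at 6 h (1 library per point, no error bars). FOSL1 peaks at 2 h with 157 and 316 FPKM, and POLR2A reaches 134 and 139 FPKM at 12 h in KYSE510 and TE7.

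The median of all tested genes shifted at 12 h by -0.27 in KYSE510 and -0.52 in TE7, and the list results below are read against it. Homologous recombination and Fanconi genes had 18 of 34 down and 0 up, 19 over the list alone, with a median of -0.95 (camera adjusted p = 0.00219, adjusted p = 0.558 with an estimated correlation); after median-of-ratios scaling 12 were down and 2 up. BRCA1 (ENSG00000012048; 17, 41196312 to 41277500), for a recombination protein, went from 17.5 to 2.54 FPKM in KYSE510 and from 29.3 to 2.16 FPKM in TE7 (adjusted p = 0.00108). BLM (-2.74 ± 0.30), FANCE (-2.46 ± 0.33) and FANCF (-2.24 ± 0.28) fell with it. Mitosis genes had 15 of 30 down and 0 up, 16 over the list alone, and a median of -1.31 (camera adjusted p = 0.00689, adjusted p = 0.729 with an estimated correlation); after median-of-ratios scaling 8 were down and 1 up. CDC25C (-2.52 ± 0.35), CDC25B (-2.23 ± 0.44) and KIF20A (-2.01 ± 0.23) were among them. G1/S genes had 6 of 27 down, 6 over the list alone, but 3 up and 1 down after that scaling, with GINS1 at -2.89 ± 0.44 and a camera adjusted p = 0.858.

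Transcription genes split at 12 h. POLR2A rose by 1.63 ± 0.20 (adjusted p = 0.0019) while POLR2D (-1.46 ± 0.31), CDK12 (-1.11 ± 0.22, adjusted p = 0.00969) and CDK9 (-1.40 ± 0.37) fell; 3 of 33 list members rose and 12 fell, 3 and 14 over the list alone, but after median-of-ratios scaling 6 rose and 0 fell. MED13 rose (adjusted p = 0.00145) while MED11 (-2.08 ± 0.22) and MED7 (-2.13 ± 0.35) fell, with 2 of 31 Mediator and BET genes up and 9 down, 3 and 9 over the list alone, and 5 and 6 after that scaling. CDK7 (-0.90 ± 0.36, adjusted p = 0.103) and CDK13 (-0.65 ± 0.25) did not pass. The zinc finger genes had 116 of 351 down and 6 up, 131 and 7 over the list alone and 76 and 20 after that scaling, with ZNF740 at -3.10 ± 0.32 and a camera adjusted p = 0.094. Spliceosome genes had 3 of 30 up and 7 down, 3 and 8 over the list alone, but 7 and 3 after that scaling, with CLK2 and SRSF1 (-1.66 ± 0.27) lower.

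Apoptosis lists were not shifted against other genes at 12 h by camera (adjusted p = 0.0854 for promoters and 0.291 for inhibitors). Among promoters 9 of 17 fell and 0 rose, 11 and 1 over the list alone and 5 and 2 after median-of-ratios scaling, including BIK (-2.26 ± 0.53), BOK (-1.95 ± 0.38) and APAF1 (-1.91 ± 0.22), with a fry adjusted p = 1.9e-05 against no change. Among inhibitors 4 of 11 fell, 4 over the list alone and 1 after that scaling, including BIRC3, BIRC2 (-1.62 ± 0.35) and XIAP (-1.28 ± 0.28). Integrated stress response genes had 7 of 24 down and 1 up, 8 and 1 over the list alone, with CEBPB (-3.16 ± 0.42), DDIT3 (-2.26 ± 0.44), DDIT4 (-3.11 ± 0.38) and XBP1 (-2.06 ± 0.19) lower. Hypoxia genes had 7 of 24 down, 10 over the list alone, NDRG1 (-2.99 ± 0.40) among them, and NF-kB genes 5 of 18 down, 5 over the list alone. Cholesterol genes had 5 of 24 down, 4 over the list alone, with MVK (-2.56 ± 0.24) lower; the camera adjusted p = 0.0326 (adjusted p = 0.793 with an estimated correlation) drew on a KYSE510 median of -1.93 against -0.36 in TE7.

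Energy and ribosome genes stood above the median gene at 12 h. Nuclear oxidative phosphorylation genes had 11 of 75 up and 3 down, 1 and 1 over the list alone and 38 and 1 after median-of-ratios scaling (camera adjusted p = 4.9e-09, adjusted p = 0.558 with an estimated correlation). NDUFA4 rose by 1.14 ± 0.21 and ATP5J2 by 1.18 ± 0.36. Ribosomal protein genes had 2 of 83 up and 1 down, 0 over the list alone and 29 and 1 after median-of-ratios scaling (camera adjusted p = 4.83e-06, adjusted p = 0.568 with an estimated correlation), with a median of 0.09 that turned to -0.08 after rescaling to equal sums. Replication-dependent histone genes had 4 of 48 up and 1 down, 0 over the list alone, with HIST1H4C at 2.70 ± 0.64 (camera adjusted p = 4.83e-06, adjusted p = 0.729 with an estimated correlation); these transcripts mostly lack poly(A) tails and share sequence, so their values are uncertain. Housekeeping genes had 2 of 15 up and 1 down, 1 and 1 over the list alone, ACTB at 0.79 ± 0.17 and TBP at -1.07 ± 0.24 (camera adjusted p = 0.0232, adjusted p = 0.688 with an estimated correlation).

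Ribosome biogenesis genes went both ways at 12 h, with 3 of 29 up and 6 down, 5 and 6 over the list alone and 11 and 1 after median-of-ratios scaling; NOP56 rose (adjusted p = 0.00596) and GNL3 fell by 1.82 ± 0.18. Their median of 0.01 became -0.14 after rescaling to equal sums, while camera placed them upward (adjusted p = 0.0326, adjusted p = 0.766 with an estimated correlation). Squamous epithelial markers had 3 of 25 down, 2 over the list alone, KRT15 (-2.58 ± 0.50) among them, yet a median of 0.23 and a camera adjusted p = 0.0326 upward (adjusted p = 0.729 with an estimated correlation). Receptor and MAPK feedback genes had 5 of 24 down, 3 over the list alone, but 3 up and 2 down after median-of-ratios scaling, with FGFR3 (-2.02 ± 0.19) and ERBB3 (-1.81 ± 0.42). Immediate-early genes had 2 of 26 up and 4 down, 2 and 4 over the list alone, YAP and TEAD targets 1 of 18 up and 3 down (1 and 2), and p53 targets 1 of 20 up and 3 down (1 and 3). Heat shock genes had 4 of 22 down (3), TGF-beta targets 2 of 17 up and 4 down (3 and 5), interferon genes 2 of 26 up and 4 down (0 and 1) and proteasome genes 1 of 38 up and 5 down (0 and 2), the figures in brackets being adjusted over the list alone. After median-of-ratios scaling immediate-early genes had 2 up and 1 down, heat shock genes 1 and 0, TGF-beta targets 3 and 1, interferon genes 4 and 1 and proteasome genes 10 and 2, so the direction of these 5 lists turns with the scaling. Squamous differentiation (12), columnar (6), mesenchymal (11) and mitochondrially encoded (13) genes had 0 changed by limma, and CD68, the only leukocyte marker tested, did not pass.

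The super-enhancer genes, which the study itself had picked and so are no independent evidence, had 2 of 5 down at 12 h and 4 over the list alone (fry adjusted p = 0.0044). PAK4 (ENSG00000130669; 19, 39616410 to 39673456), for a p21-activated kinase, fell by 1.60 ± 0.29 (adjusted p = 0.00598), from 27 to 11.5 FPKM in KYSE510 and from 35.3 to 7.86 FPKM in TE7. YAP1, the Hippo pathway coactivator gene, fell by 1.30 ± 0.36 (adjusted p = 0.0295). DNAJB1 (-1.34 ± 0.47, adjusted p = 0.0681), SREBF2 (-1.11 ± 0.44) and RUNX1 (-2.11 in KYSE510 and 0.25 in TE7) did not pass.

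At 12 h the count was 2573 or 2000 without the KYSE510 or TE7 12 h library, 1657 with no block, and 8166 without the 3 libraries that stand apart. The PAK4 call ended without the TE7 12 h library (-1.33), YAP1 ended without the library labelled KYSE510 DMSO (-0.67) and after median-of-ratios scaling (-0.81), and CDK12 ended after that scaling (-0.65).

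**Figure D3:**
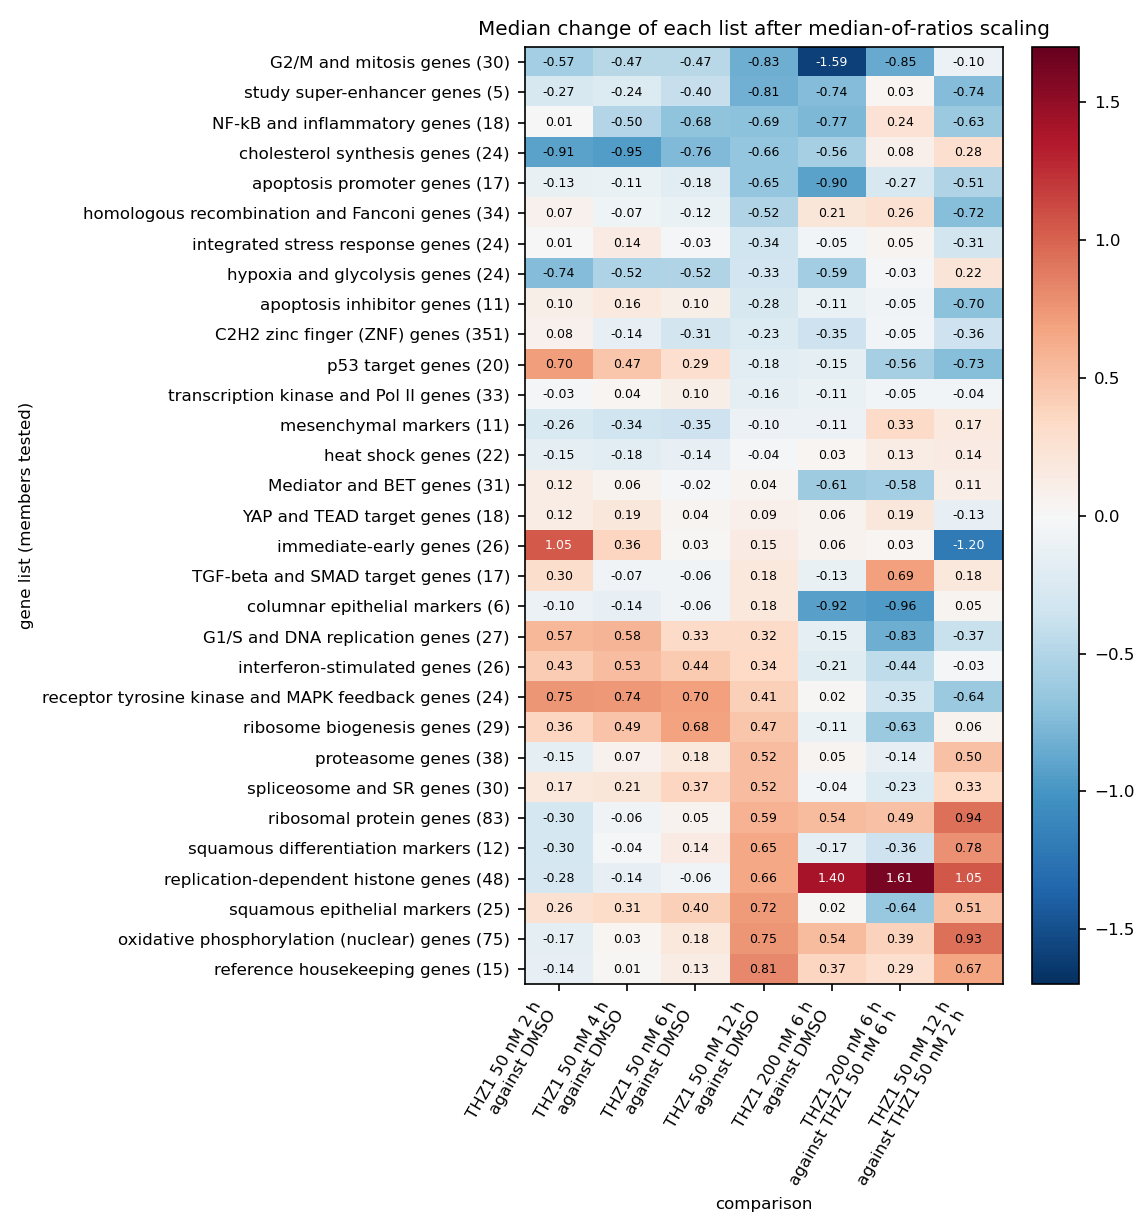
Median log2 change of each gene list with at least 5 tested members after median-of-ratios scaling, by contrast (columns) and list (lines), as colour; the mitochondrially encoded list is left out. Homologous recombination and mitosis genes lie below the other genes at 12 h, where without that scaling their medians were -0.95 and -1.31.

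The 200 nM comparison with DMSO asked what a higher dose did in 6 h. In TE7 the libraries had 662 values above 0 and under 0.0001 FPKM at 200 nM and 305 in DMSO, against 697 and 706 in KYSE510. The TE7 part of these changes thus cannot be told apart from a difference in processing. In KYSE510 the DMSO and 200 nM libraries both stood apart, so a difference between their cells cannot be told apart from dose. AURKA (ENSG00000087586; 20, 54944445 to 54967393), for a mitotic kinase, fell by 5.09 ± 0.30 (adjusted p = 0.00027), from 87.5 to 2.52 FPKM in KYSE510 and from 119 to 1.62 FPKM in TE7, and its direct neighbour CSTF1 (20, 54967427 to 54979518) fell by 3.65 ± 0.22. NDRG1 fell by 4.48 ± 0.40, TCEAL8 by 4.40 ± 0.42, the serine protease gene PRSS8 by 4.07 ± 0.24, and the TNF receptor gene TNFRSF1A by 3.83 ± 0.30. CASC19 (3.12 ± 0.67), IER3 (2.61 ± 0.35), SERPINE2 (2.28 ± 0.39), COL4A1 (2.01 ± 0.24) and P2RY11 (2.00 ± 0.21) rose. By limma 6006 genes (38.5%) passed, 503 up and 5503 down. The split depended on scaling, with 1741 up and 2062 down by median-of-ratios, 1960 and 1916 by upper quartile, 786 and 3439 rescaled to equal sums, and 923 and 3209 scaled over nuclear protein-coding genes.

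The median gene stood at -0.54 in KYSE510 and -0.71 in TE7 at 200 nM. Mitosis genes had 29 of 30 down, 29 over the list alone and 20 after median-of-ratios scaling (camera adjusted p = 2.49e-08, adjusted p = 0.804 with an estimated correlation), with CCNB1 (-3.76 ± 0.49), TTK (-3.59 ± 0.31) and PLK1 (-3.38 ± 0.46). Mediator and BET genes had 21 of 31 down, 23 over the list alone, with 1 up and 8 down after median-of-ratios scaling (camera adjusted p = 0.00558, adjusted p = 0.791 with an estimated correlation), MED11 (-2.32 ± 0.22) and MED7 (-2.25 ± 0.35) among them. Transcription genes had 16 of 33 down, 18 over the list alone, but 5 up and 2 down after that scaling, with POLR2D at -2.31 ± 0.31. Histone genes had 15 of 48 up and 0 down, 15 over the list alone (camera adjusted p = 2.02e-17, adjusted p = 0.804 with an estimated correlation), HIST1H4C (3.27 ± 0.64) and HIST3H2BB (2.42 ± 0.42) among them; the list median was 1.91 in TE7 and -0.0015 in KYSE510.

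Further lists were counted at 200 nM. The squamous master regulator gene TP63 fell by 2.53 ± 0.30, GRHL2 by 2.76 ± 0.63 and KRT15 by 4.19 ± 0.50, with 8 of 25 squamous markers down and 1 up, 8 and 1 over the list alone, and 3 and 2 after median-of-ratios scaling. Hypoxia genes had 14 of 24 down and 1 up, 15 and 1 over the list alone and 9 and 2 after that scaling, with EGLN3 (-3.78 ± 0.86) and BNIP3L (-2.72 ± 0.22). Stress response genes had 11 of 24 down, 11 over the list alone, or 7 down and 3 up after that scaling, with CEBPB (-3.36 ± 0.42) and HERPUD1 (-2.54 ± 0.31). Heat shock genes had 10 of 22 down, 10 over the list alone, or 4 down and 2 up after that scaling, with BAG3 (-3.21 ± 0.31) and HSPA8 (-2.93 ± 0.31). Apoptosis promoters had 10 of 17 down, 11 over the list alone and 6 after that scaling, with APAF1 at -2.45 ± 0.22. Apoptosis inhibitors had 5 of 11 down, 8 over the list alone and 0 after that scaling, with BIRC2 (-1.81 ± 0.35). FOS (-3.12 ± 0.61), FGFR3 (-2.78 ± 0.19), ERBB3 (-2.62 ± 0.42), GNL3 (-2.76 ± 0.18) and TUBB (-1.83 ± 0.23) fell.

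CDK7 fell at 200 nM (adjusted p = 0.00317), from 21.9 to 7.99 FPKM in KYSE510 and from 26.5 to 2.50 FPKM in TE7, and CDK13 fell by 1.16 ± 0.25 (adjusted p = 0.00848), while CDK12 (-0.63 ± 0.22, adjusted p = 0.057) did not pass. Of the study's own super-enhancer genes 3 of 5 fell, 3 over the list alone, namely PAK4 (-2.14 ± 0.29, adjusted p = 0.00132), YAP1 (-1.53 ± 0.36) and DNAJB1 (-1.89 ± 0.47), while SREBF2 (-0.54 ± 0.44) and RUNX1 (-0.26 ± 0.53) did not pass. RNA5S9, a 5S ribosomal RNA locus (1, 228763895 to 228764013), was listed at 0 in 10 libraries and at 67.8 and 36 FPKM in the KYSE510 and TE7 200 nM libraries (adjusted p = 0.00027). MIR663A (7.86 ± 1.99, adjusted p = 0.017) and ANKRD30BL (4.05 ± 1.35, adjusted p = 0.0459) rose as well, but repeated sequence at these loci leaves their values uncertain.

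Left-out libraries kept the 200 nM count within 1.5 times, and no block gave 2795. The YAP1 call ended without the KYSE510 200 nM library (-1.16) and after median-of-ratios scaling (-0.74), which also ended CDK13 (-0.48) and DNAJB1 (-1.12); MIR663A ended without the library labelled KYSE510 DMSO (6.10) and without the TE7 200 nM library (4.64).

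The dose comparison set 200 nM against 50 nM at 6 h, with no DMSO library in the difference. In TE7 the libraries had 662 values above 0 and under 0.0001 FPKM at 200 nM and 323 at 50 nM. The KYSE510 counts were 697 and 708. A difference in processing thus cannot be told apart from dose in the TE7 part of these changes. Autosome medians also shifted apart between the doses, with an SD of 0.244 in KYSE510 and 0.111 in TE7 (highest of 1000 shuffles 0.117 and 0.104). A difference between the cells of these libraries thus cannot be told apart from dose, in KYSE510 either. GTF2B (ENSG00000137947; 1, 89318615 to 89357627), the TFIIB gene, fell by 4.38 ± 0.21 (adjusted p = 0.000243), from 35.6 to 1.05 FPKM in KYSE510 and from 34.7 to 0.46 FPKM in TE7. GPRC5A fell by 4.15 ± 0.56 and AURKA by 3.43 ± 0.30. The importin gene KPNA2 (-4.02 ± 0.30), the connexin gene GJB2 (-3.43 ± 0.46), N4BP1 (-3.25 ± 0.23) and TUBA4A (-3.20 ± 0.38) fell too. MXRA8 (adjusted p = 0.00731), C21orf58 (2.29 ± 0.29), IER3 (2.05 ± 0.35), LCAT (1.83 ± 0.29), CPNE7 (1.76 ± 0.37), CPT1B (1.75 ± 0.24), EME2 (1.72 ± 0.26) and PLXNA3 (1.72 ± 0.28) rose. By limma 3871 genes (24.8%) passed, 459 up and 3412 down. The split was 1407 and 1313 by median-of-ratios, 1694 and 1159 by upper quartile, 909 and 1465 rescaled to equal sums, and 811 and 1935 over nuclear protein-coding genes.

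The median gene was at -0.45 in KYSE510 and -0.40 in TE7 in the dose comparison. Ribosome biogenesis genes, of which 2 rose and 0 fell at 6 h of 50 nM, had 20 of 29 down, 25 over the list alone and 13 after median-of-ratios scaling (camera adjusted p = 5.16e-07, adjusted p = 0.569 with an estimated correlation), with NOP16 (-3.12 ± 0.19) and GNL3 (-2.73 ± 0.18). Mitosis genes had 21 of 30 down, 26 over the list alone and 12 after that scaling (camera adjusted p = 6.76e-07, adjusted p = 0.569 with an estimated correlation), with CCNB1 (-2.88 ± 0.49) and PLK1 (-2.73 ± 0.46). Mediator and BET genes had 18 of 31 down, 20 over the list alone and 9 after that scaling (camera adjusted p = 0.000295, adjusted p = 0.415 with an estimated correlation), with MED6 (-2.17 ± 0.19), BRD2 (-2.12 ± 0.33) and MED13 (-1.95 ± 0.20). POLR2A, which had risen at 50 nM, was lower by dose at -1.92 ± 0.20 (adjusted p = 0.00102). G1/S genes had 16 of 27 down, 19 over the list alone, or 8 down and 1 up after that scaling (camera adjusted p = 0.00121, adjusted p = 0.569 with an estimated correlation), with ORC1 (-2.91 ± 0.29) and CDC6 (-2.59 ± 0.19). Spliceosome genes had 15 of 30 down, 20 over the list alone, or 7 down and 1 up after that scaling (camera adjusted p = 0.000811, adjusted p = 0.569 with an estimated correlation), with SRSF3 (-2.34 ± 0.35) and SF3B1 (-1.79 ± 0.21). Proteasome genes had 17 of 38 down, 17 over the list alone and 3 after that scaling (camera adjusted p = 0.00781, adjusted p = 0.569 with an estimated correlation), with PSMD12 at -2.41 ± 0.26.

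Heat shock genes had 5 of 22 down and 2 up by dose, 9 and 2 over the list alone, but 3 and 4 after median-of-ratios scaling. HSPA8 (-2.79 ± 0.31), BAG3 (-3.02 ± 0.31), FAS (-2.73 ± 0.59), CDKN1A (-1.73 ± 0.33), FOSL1 (-2.49 ± 0.23), MYC (-2.15 ± 0.52), KLF5 (-2.91 ± 0.47), TUBB (-1.84 ± 0.23) and ACTB (-1.11 ± 0.17) fell. Histone genes had 17 of 48 up and 0 down, 20 over the list alone (camera adjusted p = 1.29e-18, adjusted p = 0.569 with an estimated correlation), with HIST3H2BB at 3.26 ± 0.42 and HIST1H4C at 2.29 ± 0.64. PAK4 fell by 1.72 ± 0.29 and was the only 1 of 5 super-enhancer genes to pass, 1 over the list alone; DNAJB1 (-1.35 ± 0.47, adjusted p = 0.0709), YAP1, RUNX1 (-0.14 ± 0.53) and SREBF2 (0.37 ± 0.44) did not. CDK7 fell by 2.12 ± 0.36 (adjusted p = 0.00565), and CDK12 (-0.67 ± 0.22, adjusted p = 0.0644) and CDK13 (-0.39 ± 0.25) did not pass. RNA5S9 also differed between the doses (adjusted p = 0.000243), with 0 at 50 nM.

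The dose count was 882 or 1143 without the KYSE510 or TE7 50 nM library at 6 h and 1344 with no block, and the CDK7 call ended without either of those libraries. A fit without the libraries that stand apart was not possible, as both 200 nM libraries are among them.

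The comparison of 12 h with 2 h at 50 nM was added after the data were seen, since it uses no DMSO library. FOSL1 fell by 3.66 ± 0.23 (adjusted p = 0.0016), from 157 to 9.95 FPKM in KYSE510 and from 316 to 27.7 FPKM in TE7, with EGR3 (-3.60 ± 0.46), NR4A1 (-3.49 ± 0.73) and DUSP6 (-3.19 ± 0.86). The polymerase alpha gene POLA2 (-3.38 ± 0.29), TNS4 (-3.05 ± 0.62), RBM23 (-3.03 ± 0.50) and GTPBP2 also fell. EID3 (2.82 ± 0.60), HIST1H4C (2.49 ± 0.64), IER5L (2.44 ± 0.46), SNHG9 (2.12 ± 0.47), ARRDC3 (2.00 ± 0.21), NME2 (1.72 ± 0.18) and NXF1 (1.60 ± 0.26) rose. By limma 3419 genes passed, 293 up and 3126 down, against 1023 and 1212 by median-of-ratios and 1049 and 1180 by upper quartile.

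The median gene stood at -0.34 in KYSE510 and -0.46 in TE7 between 2 and 12 h. Immediate-early genes had 15 of 26 down, 15 over the list alone (camera adjusted p = 0.00199, adjusted p = 0.369 with an estimated correlation). Homologous recombination genes had 22 of 34 down, 23 over the list alone (camera adjusted p = 2.47e-06, adjusted p = 0.105 with an estimated correlation), with BRCA1 (-2.68 ± 0.26), FANCE (-2.21 ± 0.33) and EXO1 (-2.07 ± 0.25). G1/S genes had 11 of 27 down, 13 over the list alone (camera adjusted p = 0.0156, adjusted p = 0.607 with an estimated correlation), with E2F1 (-2.92 ± 0.45) and RFC4 (-2.79 ± 0.50). The p53 targets had 8 of 20 down, 9 over the list alone (camera adjusted p = 0.0358, adjusted p = 0.369 with an estimated correlation), with PLK3 (-2.77 ± 0.24), TNFRSF10B (-2.23 ± 0.25) and CDKN1A (-2.08 ± 0.33). Zinc finger genes had 101 of 351 down and 2 up, 118 and 2 over the list alone (camera adjusted p = 0.00199, adjusted p = 0.607 with an estimated correlation).

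Ribosomal protein genes had 9 of 83 up and 1 down between 2 and 12 h, 0 over the list alone and 55 and 1 after median-of-ratios scaling (camera adjusted p = 4.68e-25, adjusted p = 0.105 with an estimated correlation). Oxidative phosphorylation genes had 18 of 75 up and 1 down, 21 and 2 over the list alone (camera adjusted p = 2.24e-21, adjusted p = 0.105 with an estimated correlation), and histone genes 6 of 48 up, 0 over the list alone (camera adjusted p = 5.16e-16, adjusted p = 0.369 with an estimated correlation). Proteasome genes had 3 of 38 down, 3 over the list alone, and a median of -0.01, while camera placed them upward relative to other genes (adjusted p = 0.00198, adjusted p = 0.369 with an estimated correlation). TP63 (-2.20 ± 0.30), EGFR (-1.52 ± 0.41), MCL1 (-1.64 ± 0.39) and IL8 (-2.62 ± 0.47) fell and HSPA1B (1.43 ± 0.34) rose. PAK4 (-1.35 ± 0.29) and DNAJB1 (-1.77 ± 0.47) fell, 2 of 5 super-enhancer genes and 2 over the list alone, while YAP1 (-0.69 ± 0.36) did not pass. CDK12 fell (adjusted p = 0.00731); CDK7 (-0.88 ± 0.36) and CDK13 (-0.61 ± 0.25) did not pass.

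Between 2 and 12 h the count was 405 or 325 without the KYSE510 or TE7 2 h library, 1821 or 962 without their 12 h libraries, 2218 or 2219 without their 4 h libraries and 2240 or 2244 without their 6 h libraries. It was 786 with no block and 8609 without the 3 libraries that stand apart.

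The shared trend asked which genes had a slope over hours at 50 nM, given per 12 h. It tested the mean of the slopes of the lines, so a gene can pass on the slope of a single line. BRCA1 fell by 2.93 ± 0.21 per 12 h (adjusted p = 8.23e-05), GINS1 by 2.88 ± 0.22, FANCE by 2.56 ± 0.19, HMMR by 2.45 ± 0.24, CDC25C by 2.35 ± 0.23 and ZNF740 by 3.07 ± 0.19. HIST1H4C (2.78 ± 0.29), ID2 (2.38 ± 0.28), MED13 (1.75 ± 0.24), POLR2A (1.60 ± 0.27, adjusted p = 0.00179), ISG15 (adjusted p = 0.000594) and NDUFA4 (1.14 ± 0.16) rose. EGR1 (-2.67 ± 0.65), TP63 (-2.40 ± 0.28), BIK (-2.27 ± 0.19), GRHL2 (-2.15 ± 0.19), MED11 (-2.11 ± 0.14), BIRC3 (-1.98 ± 0.39) and STAT2 (-1.57 ± 0.17) fell. By limma 7188 genes (46%) passed, 1079 up and 6109 down, against 2929 and 3593 by median-of-ratios and 2967 and 3545 by upper quartile.

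Homologous recombination genes had 27 of 34 down with the trend, 28 over the list alone (camera adjusted p = 0.000978, adjusted p = 0.578 with an estimated correlation), and mitosis genes 22 of 30, 22 over the list alone (camera adjusted p = 0.00497, adjusted p = 0.578 with an estimated correlation). Oxidative phosphorylation genes had 29 of 75 up and 3 down, 29 and 3 over the list alone (camera adjusted p = 3.83e-14, adjusted p = 0.4 with an estimated correlation), and histone genes 17 of 48 up and 2 down, 16 and 2 over the list alone (camera adjusted p = 1.98e-12, adjusted p = 0.463 with an estimated correlation). Super-enhancer genes had 4 of 5 down, 4 over the list alone (fry adjusted p = 0.000204): PAK4 (-1.57 ± 0.20, adjusted p = 0.000557), DNAJB1 (-1.64 ± 0.37), YAP1 (adjusted p = 0.0117) and RUNX1 (-2.04 in KYSE510 and -0.17 in TE7), while SREBF2 did not pass. The RUNX1 call ended without either 12 h library. CDK7 (-0.92 ± 0.20), CDK12 (-1.23 ± 0.28) and CDK13 (adjusted p = 0.048) had negative slopes.

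The trend count was 4701 or 3549 without the KYSE510 or TE7 12 h library, 3364 without both and 3491 with no block. The CDK7 and CDK12 slopes came from 12 h, at -0.04 and 0.03 without both 12 h libraries, and each call ended without either one. The CDK7 call also ended after median-of-ratios scaling.

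A test of the difference between the slopes of the lines found 11 genes by limma, 4 with a higher slope in KYSE510 and 7 with a higher slope in TE7 (2111 had an unadjusted p under 0.05). The glucose transporter gene SLC2A10 (ENSG00000197496; 20, 45338126 to 45364965) fell from 13 to 0.95 FPKM over 12 h in TE7 and lay at or under 0.01 FPKM in KYSE510, a slope difference with an adjusted p = 0.0267. UTS2, for a vasoactive peptide, had 4.22 FPKM in TE7 DMSO and 0.22 at 12 h, with KYSE510 at or under 0.07 FPKM (adjusted p = 0.0424). ZNF22 fell from 12.9 to 2.08 FPKM in KYSE510 and was listed at 0 in TE7. LINC00657, a non-coding RNA that binds PUMILIO proteins, fell from 135 to 21.6 FPKM in KYSE510 and stood at 162 and 165 FPKM in TE7 (adjusted p = 0.0267). LENG8 rose from 51.1 to 147 FPKM in TE7 and had a slope of -0.51 per 12 h in KYSE510 (adjusted p = 0.0424 for the difference). Mitochondrially encoded genes had 3 of 13 with a higher TE7 slope, 12 over the list alone (camera adjusted p = 4.47e-23, adjusted p = 0.211 with an estimated correlation), MT-CYB among them. MT-CYB and 9 others were listed at 0 in all KYSE510 libraries.

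Slope-difference calls left 0 genes without any 1 of the 2, 4 or 6 h libraries, 2 without TE7 DMSO, 5 or 4 without the KYSE510 or TE7 12 h library, and 269 without the library labelled KYSE510 DMSO. After median-of-ratios scaling 45 genes passed and after rescaling to equal sums 0.

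The line comparison asked how KYSE510 differs from TE7 over all conditions. The lines also differ in medium, which cannot be told apart from line here. Values above 0 and under 0.0001 FPKM numbered 662 to 728 in KYSE510 and TE7 at 200 nM, and 290 to 323 in the other TE7 libraries. A difference in processing thus goes almost wholly with line. SGK1, a kinase gene, was higher in KYSE510 by 4.41 ± 0.37 (adjusted p = 0.000209), with MFAP5 (5.52 ± 0.68), NTRK2 (5.03 ± 0.73), OLFM2 (4.38 ± 0.47) and the cancer-testis antigen genes MAGEA3 (4.92 ± 0.60) and CTAG2 (4.64 ± 1.17). UCHL1 differed by 7.07 ± 1.13. The library labelled KYSE510 DMSO did not share all of these, with UCHL1 at the TE7 level, CTAG2 at 0.07, NTRK2 at 0.50, MFAP5 at 1.85 and OLFM2 at 2.87 FPKM. At 200 nM CTAG2 was 0 and MAGEA3 1.36 FPKM in KYSE510. PRSS3 (-6.69 ± 0.19), CRIP1 (-6.45 ± 0.31), CA2 (-6.24 ± 0.70) and TUSC3 (adjusted p = 0.00102) were higher in TE7. KYSE510 had 35 FPKM of CA2 in DMSO and 81.8 FPKM of TUSC3 at 200 nM. By limma 7232 genes (46.3%) passed, 2728 higher in KYSE510 and 4504 in TE7, against 4438 and 2727 after rescaling to equal sums and 3307 and 3758 by median-of-ratios.

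Cholesterol synthesis genes were higher in KYSE510, with 11 of 24 and 0 the other way, 13 and 1 over the list alone (camera adjusted p = 0.000102, adjusted p = 0.86 with an estimated correlation), including STARD4 (2.39 ± 0.40) and INSIG1 (2.36 ± 0.24). Squamous epithelial markers had 9 of 25 higher in KYSE510 and 1 in TE7, 9 and 1 over the list alone, with KRT15 (2.83 ± 0.29), SOX2 (2.40 ± 0.74) and DSG3 (1.79 ± 0.31; camera adjusted p = 0.039, adjusted p = 0.86 with an estimated correlation). Squamous differentiation markers had 2 of 12 higher in KYSE510 and 6 in TE7, 2 and 6 over the list alone, with LCN2 at 3.46 ± 0.64, SPRR1B at -2.18 ± 0.44 and KRT10 at -1.86 ± 0.13. Hypoxia genes had 10 of 24 higher in KYSE510 and 3 in TE7, 12 and 3 over the list alone, with BNIP3 (3.80 ± 0.29) and ALDOC (3.19 ± 0.25). Homologous recombination genes had 16 of 34 higher in TE7 and 1 in KYSE510, 16 and 1 over the list alone (camera adjusted p = 0.039, adjusted p = 0.86 with an estimated correlation), with XRCC3 (-1.88 ± 0.13) and FANCA (-1.28 ± 0.19).

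Columnar markers had 4 of 6 higher in KYSE510 and 1 in TE7, and mesenchymal markers 2 of 11 and 3, with COL1A1 at 2.35 ± 0.16 and TWIST1 at -2.36 ± 0.27. YAP and TEAD targets had 3 of 18 higher in KYSE510, CTGF (3.59 ± 0.43) among them, and 8 in TE7. Interferon genes had 4 of 26 and 11, 5 and 11 over the list alone, with IFI6 at 1.93 ± 0.20 and ISG15 at -3.03 ± 0.32. PSMB9, for an immunoproteasome subunit, was higher in KYSE510 by 3.66 ± 0.37. All 13 mitochondrially encoded genes passed as higher in TE7, but 10 of them, MT-CO2 and MT-CO1 included, were listed at 0 in the 6 KYSE510 libraries and in TE7 at 200 nM, so they are not read as a difference between the lines.

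The line count was 4292 with no block and 4024 among genes with a mean FPKM of at least 5, and left-out libraries kept it within 1.5 times.

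**Figure D4:**
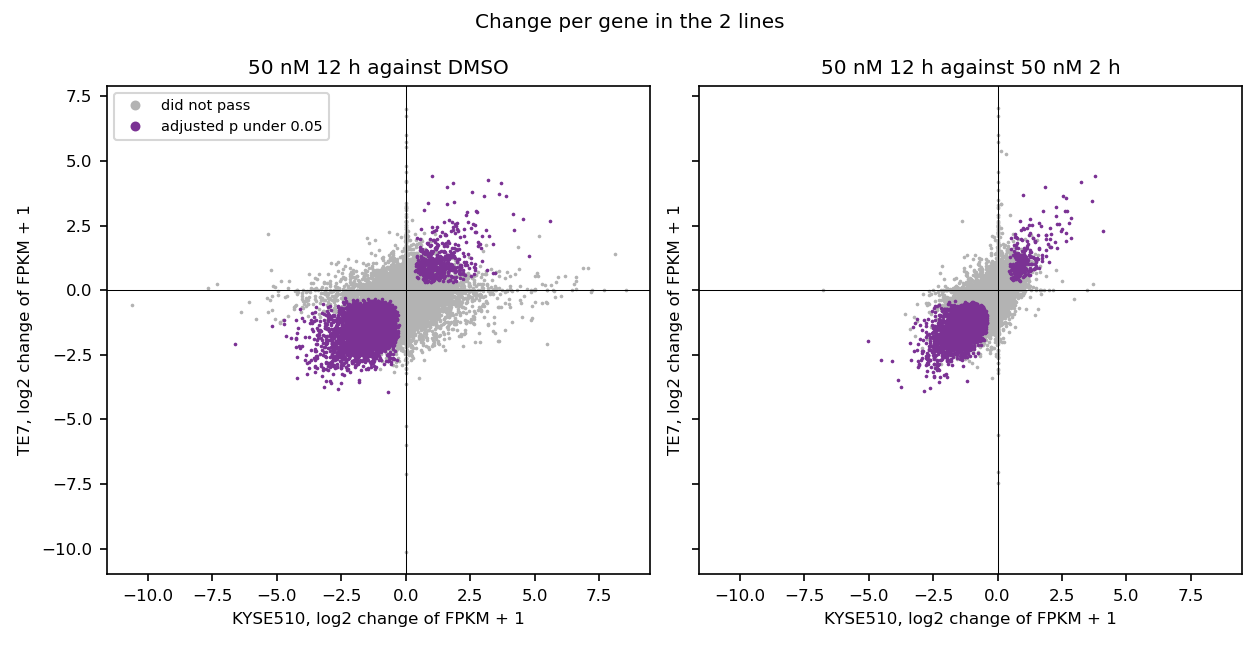
Log2 change in KYSE510 (horizontal) against TE7 (vertical) for genes outside chromosome Y, in the comparisons of 12 h with DMSO and of 12 h with 2 h, 1 point per gene. Across genes r was 0.468 against DMSO and 0.69 against 2 h.

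Without a test, 2-fold changes in both lines were counted for each contrast with DMSO. At 2 h 97 genes were higher and 71 lower in both lines, where independent lines would give 29.9 and 25. At 4 h the counts were 100 and 268 (36 and 89 if independent), at 6 h 127 and 663 (43.4 and 243), at 12 h 206 and 2347 (53.2 and 1185), and at 200 nM 195 and 3190 (44.2 and 2007).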

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

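The tests of different processing, of another origin of the cells, of the mitochondrial genes and of the splits by time were chosen after the result was seen, and the scaling over nuclear protein-coding genes was added after the data were seen; the test of a response to THZ1 was chosen before.

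The slope over hours of 50 nM THZ1 differed between KYSE510 and TE7 by a limma test of the difference in 11 genes, 8 of them with ordinary gene names. SLC2A10 (2.895 per 12 h, KYSE510 minus TE7) and UTS2 (2.227) fell in TE7 only and were near 0 in KYSE510. LINC00657 (-2.529) and ZNF22 (-2.21) fell in KYSE510, ZNF22 being listed at 0 in TE7. LENG8 (-2.007) rose in TE7. MT-ND4L (-1.934), MT-CYB (-1.902) and MT-CO2 (-1.759) rose in TE7 and were listed at 0 in KYSE510, so their difference says nothing about KYSE510. The test chosen before, over 100 splits of the 10 libraries, decides nothing, since splits that mix the lines put the line differences into the error. The splits that part both libraries of every time number 16, too few for a share under 0.05. The real one gave 11 genes, and of the others the one that swaps the 12 h libraries gave 2541. That swap puts the line difference at 12 h, the latest time, into the slopes by construction, so its count cannot be set against 11.

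Genes at least 2-fold up in one line and 2-fold down in the other were counted at each contrast with DMSO, with no test of the difference. There were 38 such genes at 2 h, 63 at 4 h, 83 at 6 h, 141 at 12 h and 230 at 200 nM. Independent lines with these numbers of changed genes would give 57.4, 127.4, 248.4, 600.5 and 645.1, so each count lay below that. RUNX1 at 12 h, at -2.11 in KYSE510 and 0.25 in TE7, moved apart in the same way without reaching 2-fold in TE7.

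The first pattern weighed is the 111 genes that switch between the library labelled KYSE510 DMSO and the 50 nM libraries, against 5 in TE7. In TE7 the 200 nM library alone was low in 71 genes and high in 27 by the same bounds. A different processing of the library labelled KYSE510 DMSO is argued against but not excluded. Whole autosomes shifted by different amounts, with an SD of their medians 3.371 times that in TE7. The spread over all genes was wider in KYSE510 too (SD 1.016 against 0.4515), and a technical bias that differs between autosomes was not tested. Cells of another origin or a diverged stock would give such shifts, and the SD of 0.1945 lay above the highest of 1000 shuffles (0.0894), whereas from 2 to 12 h in KYSE510 it was 0.0632 (0.0909 in shuffles). Against that reading, TE7 at 2 h (0.0577, shuffles 0.0406) and both 200 nM libraries against 50 nM (0.244 and 0.111, shuffles 0.117 and 0.104) shifted by autosome as well. A response to THZ1 cannot be told apart from this, because 60.4% of the switched genes stood nearer the 50 nM libraries at 200 nM, between the bounds set for it; a swap with TE7 DMSO is argued against by r with the 2 h libraries, 0.879 in its own line and 0.820 in TE7, and by TE7 DMSO, at 0.976 with TE7 and 0.820 with KYSE510.

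The second pattern is the mitochondrially encoded genes, 8.88% to 27.3% of FPKM in 5 TE7 libraries and under 0.143% in the 7 others. Processing that left out the whole mitochondrial chromosome is argued against by MT-ATP6, at 41.66 FPKM or more in each of the 7 and at 545.5 and 198 FPKM at 200 nM, with MT-CO3 and MT-ND4 above 0. A loss in the cells is argued against by MT-ATP8, which lies on 1 transcript with MT-ATP6 and was listed at 0 in all 7, but at 1.52 to 1.74 times MT-ATP6 in the 5. A difference in processing of another kind would go with the count of values above 0 and under 0.0001 FPKM, which parted the 7 from the 5 by a gap of 339, but its nature stays open. RN7SL2 and RMRP, nuclear non-coding genes, were listed at 0 in the same 7 libraries. Since TE7 at 200 nM is 1 of the 7, the rise of MT-CYB with hours in TE7 has no counterpart at the higher dose.

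The third pattern is that more genes fell than rose at 12 h of 50 nM, BRCA1 and HMMR among the falls. Mitochondrial and ribosomal RNA taking part of the total in the authors' scaling is argued against as the whole cause. After scaling over nuclear protein-coding genes 6.4 genes still fell for each that rose. That scaling also divides by a sum, which abundant nuclear genes can set, so the authors' scaling as such is not excluded. The balance depends on scaling all the same, with 2003 lower and 1455 higher by median-of-ratios and 1942 and 1473 by upper quartile, which both set the median gene near 0. A fall of RNA output through CDK7 inhibition remains a hypothesis, and FPKM holds no absolute amount of RNA to test it.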

How the results depend on the processing

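For the 365 pairs of a named gene and a comparison, 9023 repeats under other settings left direction and side of the threshold as they were in 7917, ended the call in 928, added one in 125 and turned the sign in 53. The comparison of 12 h with 2 h and the settings without the 3 libraries that stand apart and over nuclear protein-coding genes were chosen after the data were seen. The cause of a change was not tested unless named. With 2 libraries per condition and 5 residual degrees of freedom, leaving out a library removes degrees of freedom as well as its values, and depth limits genes near 1 FPKM most: the median upper bound was 7.29% to 10.6% above the value. The whole-series table was not run as an alternative. The slope difference has no form with no replicate block, since the line term is part of it, and the 200 nM contrasts cannot be fitted without the libraries that stand apart.

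Leaving out 1 library at a time gave ranges of 0 to 1717 genes at 2 h, 0 to 1991 at 4 h, 0 to 2556 at 6 h, 2000 to 5949 at 12 h, 4952 to 6653 at 200 nM against DMSO, 882 to 5311 at 200 against 50 nM, 325 to 5008 at 12 h against 2 h, 4981 to 8270 between lines, 3549 to 9597 for the shared trend and 0 to 269 for the slope difference. Against main counts of 2, 12, 736, 4439, 6006, 3871, 3419, 7232, 7188 and 11, the calls that never ended in any run included POLR2A, BRCA1, NXF1, MED13 and LPCAT1 at 12 h and AURKA at 200 nM.

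The block for cell line holds by design, since the same-numbered libraries come from the same line. With no replicate block the counts were 0 at 2 h, 0 at 4 h, 0 at 6 h, 1657 at 12 h, 2795 at 200 nM against DMSO, 1344 between doses, 786 at 12 h against 2 h, 4292 between lines and 3491 for the trend, with 6 lists shifted at 12 h against 11. The line differences then enter the error, by construction.

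Without the 3 libraries that stand apart DMSO is the TE7 library alone, so the spread comes from the other conditions, and the counts were 195 at 2 h, 1665 at 4 h, 3819 at 6 h, 8166 at 12 h, 8609 at 12 h against 2 h and 269 for the slope difference. DHCR7 (0.12) and DNAJB1 (-0.13) turned at 2 h, CDK7 (-0.14) and CDK12 (-0.046) at 4 h, CDK12 (-0.18) at 6 h and RUNX1 (0.079) at 12 h, none past the threshold.

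Pseudocounts changed short counts and 2-fold counts. With 0.1 there were 1 gene at 2 h, 5 at 4 h, 427 at 6 h and 1 for the slope difference, and 2-fold counts in both lines of 460 at 2 h, 931 at 4 h, 1646 at 6 h and 3885 at 12 h. With 5 there were 8 genes at 2 h, 119 at 4 h and 23 for the slope difference, and 2-fold counts of 47, 69, 145, 848 and 1495 at 2, 4, 6 and 12 h and 200 nM. Main 2-fold counts were 168, 368, 790, 2553 and 3385, and 4-fold changes numbered 11, 15, 40, 317 and 603. A larger pseudocount shrinks the change of low genes by construction.

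With no filter 17 genes passed at 2 h, 27 at 4 h, 405 at 6 h and 20 for the slope difference, and 18 lists were shifted at 200 nM against DMSO and 19 between doses. With a mean FPKM of at least 5 the counts were 1 at 2 h, 3 at 4 h, 230 at 6 h, 2859 at 12 h, 4024 between lines, 4441 for the trend and 3 for the slope difference, in fewer genes tested. The 2-fold counts were then 104, 159, 372 and 1550 at 2, 4, 6 and 12 h, and 5 lists were shifted at 6 h and 5 at 12 h. The span correlation became -0.0187 between doses and -0.0425 at 12 h against 2 h in KYSE510. In TE7 it turned to 0.0447 at 12 h (main -0.0347), 0.0444 at 200 nM (-0.0357), 0.00792 between doses (-0.063) and 0.0171 at 12 h against 2 h (-0.0711).

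Rescaled to equal sums, 1 gene passed at 2 h, 0 at 4 h, 2374 between doses and 0 for the slope difference, 6 lists were shifted at 200 nM against DMSO, and the 2-fold count was 1253 at 6 h. CDK7 (0.062) and CDK13 (0.035) turned at 2 h, CDK12 (-0.075) at 6 h, RUNX1 at 200 nM against DMSO (0.097), and RUNX1 (0.34) and CDK13 (0.021) between doses. Over nuclear protein-coding genes 0 genes passed at 4 h, 431 at 6 h and 0 for the slope difference, with 6 lists at 200 nM and 2-fold counts of 264 at 2 h and 559 at 4 h. CDK7 (0.093) and CDK13 (0.064) turned at 2 h, CDK7 (0.011) at 6 h, and RUNX1 at 200 nM against DMSO (0.18) and between doses (0.25).

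Median-of-ratios scaling gave 1 gene at 2 h, 1 at 4 h, 359 at 6 h, 3803 at 200 nM against DMSO, 2235 at 12 h against 2 h and 45 for the slope difference, with 6 lists and 1895 2-fold genes at 200 nM. CDK7 turned at 6 h (0.092), CDK12 (0.12), SREBF2 (0.23) and RUNX1 (0.51) at 200 nM against DMSO, and RUNX1 (0.49), CDK13 (0.17) and YAP1 (0.033) between doses. Upper-quartile scaling gave 1, 1, 360, 3876, 2229 and 45 genes in the same order, with 6 lists and 1910 2-fold genes at 200 nM. CDK7 turned at 6 h (0.072), CDK12 (0.19), SREBF2 (0.30) and RUNX1 (0.57) at 200 nM against DMSO, and RUNX1 (0.58), CDK12 (0.037), CDK13 (0.25) and YAP1 (0.12) between doses. Both set the median gene near 0 by construction.

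With an estimated correlation 0 lists were shifted in each of the 8 contrasts, against 13 at 2 h, 10 at 4 h, 9 at 6 h, 11 at 12 h, 3 and 7 at 200 nM, 12 at 12 h against 2 h and 10 for the trend. For the slope difference 1 gene passed without a variance trend, 5 with robust variances, 5 on log2 hours, 0 without the 12 h libraries and 956 without the DMSO libraries. The trend had 3364 genes without the 12 h libraries, where CDK12 turned to 0.034 from a call at -1.23. CDK12 was the only called gene that turned in any setting.

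Single left-out libraries turned further signs, none of a called gene, and these genes had the following ranges. At 2 h DHCR7 ran from -4.73 to 0.017 and YAP1 from -1.24 to 0.026, each higher without the library labelled KYSE510 DMSO, and RUNX1 from -0.62 without TE7 DMSO to 1.20. CDK7 at 2 h ran from -0.32 to 0.30 (0.15 without the KYSE510 2 h library) and CDK13 from -0.18 to 0.11 (0.045 without the TE7 2 h library). At 4 h CDK7 ran from -0.26 to 0.35 (-0.086 without the TE7 4 h library) and CDK12 from -0.056 to 0.40. At 6 h CDK7 ran from -0.35 to 0.27 and CDK12 from -0.19 to 0.27, with 0.028 and -0.086 without the KYSE510 6 h library. At 200 nM against DMSO SREBF2 ran from -1.20 to 0.13 and RUNX1 from -1.17 to 0.65 (0.058 without the TE7 200 nM library). Between doses SREBF2 ran from -0.073 to 0.81 and RUNX1 from -0.57 to 0.28 (0.17 without the TE7 200 nM library).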

Other observations

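The test by splits of the lines was chosen before the result was seen. The span test uses the 12 h to 2 h comparison, which was added after the data were seen, and the non-coding genes were picked after their values were seen.

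MIR3648 (21, 9825832 to 9826011) in TE7 was 44.5 FPKM in DMSO and 43, 295, 1596 and 5824 FPKM after 2, 4, 6 and 12 h of 50 nM THZ1, and was listed at 0 in the 7 libraries with most mitochondrial genes at 0. MIR663A (20, 26167556 to 26232162) in KYSE510 was 2.03 FPKM in DMSO and 20.1, 89.9, 201 and 276 FPKM at those hours, and at most 0.18 FPKM in TE7 at 50 nM but 539 FPKM at 200 nM. TE7 at 200 nM is 1 of those 7 libraries and TE7 at 50 nM is not, so processing cannot be told apart from dose in that MIR663A difference. CCAT1 in KYSE510 was 0.11 FPKM in DMSO and 152 FPKM at 2 h, then 139, 85.4 and 21.6 FPKM. It is among the genes that switch between the library labelled KYSE510 DMSO and the 50 nM libraries, so the size of that rise rests on that library. In TE7 CCAT1 was 4.58 FPKM in DMSO and 23.8 to 29.2 FPKM from 2 to 6 h. RN7SK in TE7 was 9.59 FPKM in DMSO and 34.5 FPKM at 12 h. RPPH1 in TE7 was 5.84 FPKM in DMSO and 19.3 FPKM at 6 h, and RMRP 3.66 and 1.73 FPKM. MIR3648, RN7SK, RPPH1 and RMRP are short loci, and each value is from 1 library.

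Longer genes were asked to fall more under THZ1, since CDK12 and CDK13 act on elongation. Between 2 and 12 h of 50 nM the Spearman rho of genomic span with the change was -0.0992 in KYSE510 and -0.07107 in TE7, so the bound of -0.1 in both lines was not met. Against DMSO, KYSE510 was past it at 12 h (-0.1275) and at 200 nM (-0.1641), as between the doses (-0.1078), with TE7 at -0.03466, -0.03572 and -0.06302. In genes with a mean FPKM of at least 5 the TE7 value from 2 to 12 h was 0.0171.

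The genes that differ between KYSE510 and TE7, SGK1 and PRSS3 among them, were counted again in the 32 splits that part both libraries of every condition. Only the real split, 1 of 32, gave as many as 7232 genes, and the highest other, which swaps the 200 nM libraries, gave 1391. That is the smallest share 32 splits can reach, so chance is argued against but not excluded. The splits cannot part the lines from their media, or from a difference in processing between KYSE510 and all TE7 libraries except 200 nM.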
